A study of Vitis riparia with 12 samples.

How the data were processed

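Shoot tips of Vitis riparia (genotype PI588259) were sampled in 12 libraries, 3 in each of the groups LD7, SD7, LD21 and SD21. Per the labels' protocols, potted vines 6 years old grew under a photoperiod of 15 h for 30 days, were randomized to the treatments, and 5 days later either stayed at 15 h or moved to 13 h. Tips were collected in the morning at days 7 and 21, each replicate from 5 vines. Total RNA was extracted on columns and treated with DNase, and libraries were sequenced on an Illumina HiScanSQ with reads of 43 bp, per the labels' protocols.

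The deposited values are FPKM for each gene and library, per the file headers, with a locus and a status that read OK for every gene. Per the submitters' processing notes, FastQC 0.11.3, cutadapt 1.8.1, Bowtie2 2.2.4, TopHat2 2.0.13 and Cufflinks 2.2.1 were used by the authors, with no parameters recorded in the sources used here. The genome build and gene annotation are not given in the sources used here. FPKM divides by transcript length and by mapped reads, so a few very abundant genes lower the values of all others in a library, and very short loci carry uncertain values with short reads. How reads were shared among near-identical or overlapping genes, and whether strand was used, are not given in the sources used here.

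Each library was taken from its own file and joined by gene identifier. The value column of SD21 replicate 3 is headed as replicate 2, but its values differ from those of replicate 2, and it was used as replicate 3. No library was a copy of another in its group, since at most 1 nonzero value was identical between libraries of a group. None of the 29970 identifiers matched the reference gene table (assembly EGFV_Vit.rip_1.0, 0 matched), and only 1 of 19 chromosomes had the same extent within 1%, so no gene names, and no coordinates of that table, were used. Coordinates are those of the files.

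Genes at 1 FPKM or more in at least 3 libraries were tested (21848) on log2(FPKM + 1). Fold changes are on that scale, which understates the change of low genes. A group means model over all 12 libraries was fitted with limma 3.58.1 in R 4.3.3, with eBayes moderation (trend and robust), and Benjamini-Hochberg adjusted p under 0.05 was called. The groups share 1 estimate of the spread because 3 libraries give few degrees of freedom. The groups, tests, the rule for named genes and most alternatives were fixed before the data were examined. Contrasts were SD7 against LD7, SD21 against LD21, their difference, LD21 against LD7 and SD21 against SD7. Overlaps of calls were tested with Fisher's exact test, two-sided, adjusted over the 8 tests. Python 3.11.15 and matplotlib 3.10.9 drew the plots.

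The rule for named genes took called genes with the largest rises and falls whose libraries did not overlap and whose higher group averaged 5 FPKM or more. Because identifiers could not be paired with names, it took 2 that rose and 2 that fell in each comparison. The gene list tests planned for fixed pathways and tissue markers need gene names and were not run. A value of 0 was taken only as listed at 0, because 13 genes above 20 FPKM in at least 10 libraries were at 0 in another, and no fold is given against a group at 0.

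Runs of neighbouring genes were sought after seeing the data. Windows of 10 consecutive tested genes on the 19 numbered chromosomes (19646 genes) were scored for genes called at least 4-fold in 1 direction. Windows above the 95th percentile of the maximum over 1000 random reorderings were joined into regions. Each region was cut to its first and last such gene, so its number of tested genes is set by the changed genes themselves. The permutation p is for the densest window of a direction, and single regions have no p of their own. For SD7 against LD7 called genes of any fold were used.

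Absolute depth is unknown. Ratios of low genes (mean below 0.3 FPKM) between libraries fell on ratios of whole numbers up to 5 within 0.005 on the log2 scale for 50.8% to 60.7% of genes, against 1.28% to 2.46% at a shifted position, and gave the relative depths. No counting interval can be given from FPKM, and the p-values measure the spread between replicates.

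The model was tested on simulated data with known changes. Each comparison had 200 changed genes, none of them low, and independent noise of the same spread in every group. The recovery and false calls below hold for that setting. SD21 against LD21, with 68.3% of genes called, lies far from it. For SD7 against LD7 (21055 genes) 24%, 72%, 94% and 98% of genes changed 1.5-, 2-, 4- and 8-fold were recovered, with 2.04% false calls. For SD21 against LD21 (20971 genes) the shares were 16%, 78%, 96% and 96%, with 4.03% false calls. The scan found 3 of 3 planted runs and 0 where none was planted. Alternatives were quantile normalization, limma without the trend, no filter on low values, a pseudocount of 0.1, only the groups compared, the replicate number as a block, each library left out, a 2-fold limit and an adjusted p of 0.01. Median-ratio scaling, totals without the most abundant genes, the choice of the 100 most abundant genes on groups outside a comparison and other windows for the scan were added after seeing the data.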

Results

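Transcript abundance was measured by RNA sequencing in shoot tips of the grapevine Vitis riparia kept under a long photoperiod of 15 h (LD) or moved to a short photoperiod of 13 h (SD). Shoot tips spanning 4 nodes were collected after 7 and 21 days of differential photoperiod, which gave the groups LD7, SD7, LD21 and SD21 with 3 libraries each, every library from a replicate of 5 vines. Shortening days lead to growth cessation and bud dormancy in this species, and the series asks how the shoot tip transcriptome responds to the photoperiod. Each library listed FPKM (fragments scaled by transcript length and by mapped reads) for 29970 gene identifiers, and 21848 genes reached 1 FPKM or more in at least 3 libraries and were tested. The identifiers could not be paired with gene names here, so genes are given by identifier and position, and broader changes by genomic region and abundance class. The absolute depth is unknown, and relative depth, recovered from whole-read steps of low genes, ran from 1.00 in LD7 replicate 1 to 1.58 in SD7 replicate 1. FPKM totals ran from 982454 in LD21 replicate 2 to 1106294 in SD21 replicate 2.

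The SD21 shoot tips stood apart from all other samples. On the first principal component, which held 66.8% of the variance, the 3 SD21 libraries lay between 131 and 155, and the 9 libraries of LD7, SD7 and LD21 lay between -77.8 and -26.2. The second component, with 11.1%, placed the LD21 libraries between -59.3 and -42.0 and the day 7 libraries between 8.12 and 41.3. Correlations of log2(FPKM + 1) between libraries were 0.971 to 0.986 within groups, 0.972 to 0.980 between LD7 and SD7, and 0.819 to 0.875 between LD21 and SD21.

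**Figure D1:**
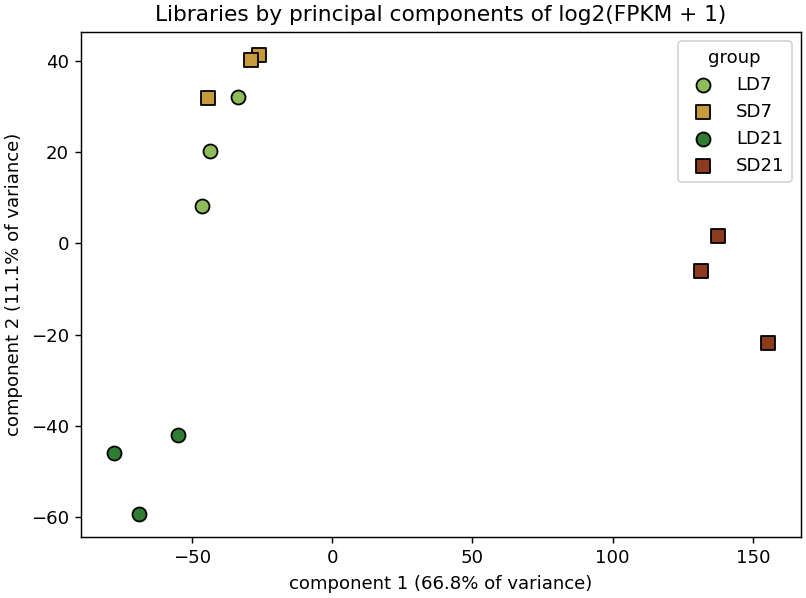
Principal components of log2(FPKM + 1) over the tested genes, with 1 point per library, first component on the horizontal axis (66.8% of variance) and second on the vertical axis (11.1%). The 3 SD21 libraries lie above 131 on the first component and the other 9 at or below -26.2.

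In SD21 the most abundant genes held a larger share of the FPKM than in the other groups, with 8.84% of it in 1 locus given below. The 10 most abundant genes of each library held 18.3% ± 2.67 (SD, n = 3) of the FPKM in SD21, 5.24% ± 0.54 in LD21, 9.63% ± 0.28 in SD7 and 8.70% ± 0.31 in LD7. Genes at 1 FPKM or more numbered 19424 to 19595 in the SD21 libraries and 20144 to 20524 in the others, and the median FPKM was 3.83 ± 0.12 in SD21 against 5.41 ± 0.20 in LD21. No SD21 library overlapped an LD21 library in these 3 measures, though 3 libraries against 3 cannot give an exact two-sided permutation p below 0.10.

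The most abundant SD21 locus, on chromosome 19 at 2789636 to 2790200, reached 96037 ± 30304 FPKM (SD, n = 3) in SD21 and 617 ± 359 in LD21, and alone held 8.84% ± 2.80 of the SD21 FPKM. Its log2 fold change was 7.38 ± 0.39 (SE, adjusted p = 7.1e-08) in SD21 against LD21. The neighbouring locus at 2785038 to 2789636, which touches it, rose from 59.0 ± 38.6 to 6804 ± 3885 FPKM (log2 fold change 6.81 ± 0.51, SE, adjusted p = 7.3e-07), and reads at the shared boundary could count toward either. A locus on chromosome 17 at 3623302 to 3624351 stood at 27621 ± 1324 FPKM in LD7, 29580 ± 2524 in SD7 and 30759 ± 3290 in SD21, and at 7337 ± 1872 in LD21. It therefore fell with time under LD (log2 fold change -1.94 ± 0.19, SE, adjusted p = 0.00055), while SD21 against SD7 gave 0.05 ± 0.19 with an adjusted p of 0.82. These 3 loci were singled out after their values were seen.

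At day 7 the photoperiod difference was small. Under SD7, 78 genes were higher and 104 lower than under LD7. The named gene with the largest rise, VIT_00s0179g00150 (Un, 7416096 to 7419674, on sequence not placed on a chromosome), went from 4.03 ± 1.48 FPKM (SD, n = 3) in LD7 to 31.9 ± 15.1 in SD7, a log2 fold change of 2.64 ± 0.50 (SE, adjusted p = 0.044). VIT_13s0064g00350, a locus of 136 bp on chromosome 13 at 21878523 to 21878658, rose from 68.2 ± 10.9 to 203 ± 36.7 FPKM (1.55 ± 0.27, adjusted p = 0.036). VIT_18s0001g02360 (18_random, 2669882 to 2677720) fell from 37.1 ± 22.3 to 5.08 ± 1.69 FPKM (-2.52 ± 0.43, adjusted p = 0.035), and VIT_03s0063g02620 (chromosome 3, 5847818 to 5849159) from 17.0 ± 7.84 to 2.40 ± 0.97 FPKM (-2.36 ± 0.32, adjusted p = 0.017).

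Among the called genes, 24 rose and 56 fell at least 2-fold, and 1 rose and 6 fell at least 4-fold. The 3 SD7 libraries did not overlap the 3 LD7 libraries in 24.8% of tested genes, where chance gives 10%, and 3258 genes had an unadjusted p under 0.05. Quantile normalization turned the split to 94 higher and 79 lower. The count of 182 depended on single libraries of either day, and on processing choices given below. It was 1 without LD7 replicate 1, 0 without LD7 replicate 2 (limma, with 2158 genes at an unadjusted p under 0.05), 10 without LD7 replicate 3, 28, 11 and 103 without SD7 replicates 1, 2 and 3, 69 without LD21 replicate 2 and 100 without SD21 replicate 1. The call of VIT_03s0063g02620 was lost without LD7 replicate 1 (adjusted p = 0.0581), LD7 replicate 2 (0.0947) or SD7 replicate 2 (0.0744), and those of the other 3 named genes were lost without any 1 of the 6 day 7 libraries, with adjusted p up to 0.146, 0.155 and 0.131 in the order above. VIT_00s0179g00150 also lost its call without LD21 replicate 2 (adjusted p = 0.0641) or SD21 replicate 1 (0.0605), 2 (0.0544) or 3 (0.0557), and VIT_18s0001g02360 without LD21 replicate 2 (0.0588). Processing choices ended calls as well, and those lost with the replicate number as a block are given below. VIT_00s0179g00150 lost its call in limma without the trend (adjusted p = 0.051), without the filter on low values (0.0591), with a pseudocount of 0.1 (0.0603), with only the groups compared (0.0508) and with median-ratio scaling (0.05 after rounding). VIT_13s0064g00350 lost its call without the filter (0.0501). VIT_18s0001g02360 and VIT_03s0063g02620 lost theirs with a pseudocount of 0.1 (0.167 and 0.0897) and with only the groups compared (0.0656 and 0.0504).

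By day 21 the shoot tips of the photoperiods differed in most of the transcriptome. VIT_00s0256g00100, a locus of 259 bp (Un, 18167341 to 18167599), stood at 829 ± 499 FPKM (SD, n = 3) in SD21 and at 1.18, 0 and 2.82 in the LD21 libraries (log2 fold change 8.49 ± 0.77, SE, adjusted p = 4.2e-06), and VIT_00s0226g00170 (Un, 14949259 to 14950130) at 579 ± 397 in SD21 and at 0, 0.494 and 0.850 in the LD21 libraries (8.39 ± 0.59, adjusted p = 4.5e-07). In the other direction, VIT_07s0130g00030 (chromosome 7, 20130292 to 20131700) fell from 2048 ± 343 FPKM in LD21 to 2.76 ± 1.22 in SD21 (-9.13 ± 0.30, adjusted p = 1.7e-08). VIT_09s0018g00510, a locus of 143 bp on chromosome 9 at 16727010 to 16727152, stood at 492 ± 50.6 FPKM in LD21 and was listed at 0 in each of the 3 SD21 libraries (adjusted p = 2.5e-09). All 4 kept their calls with each library left out.

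**Figure D2:**
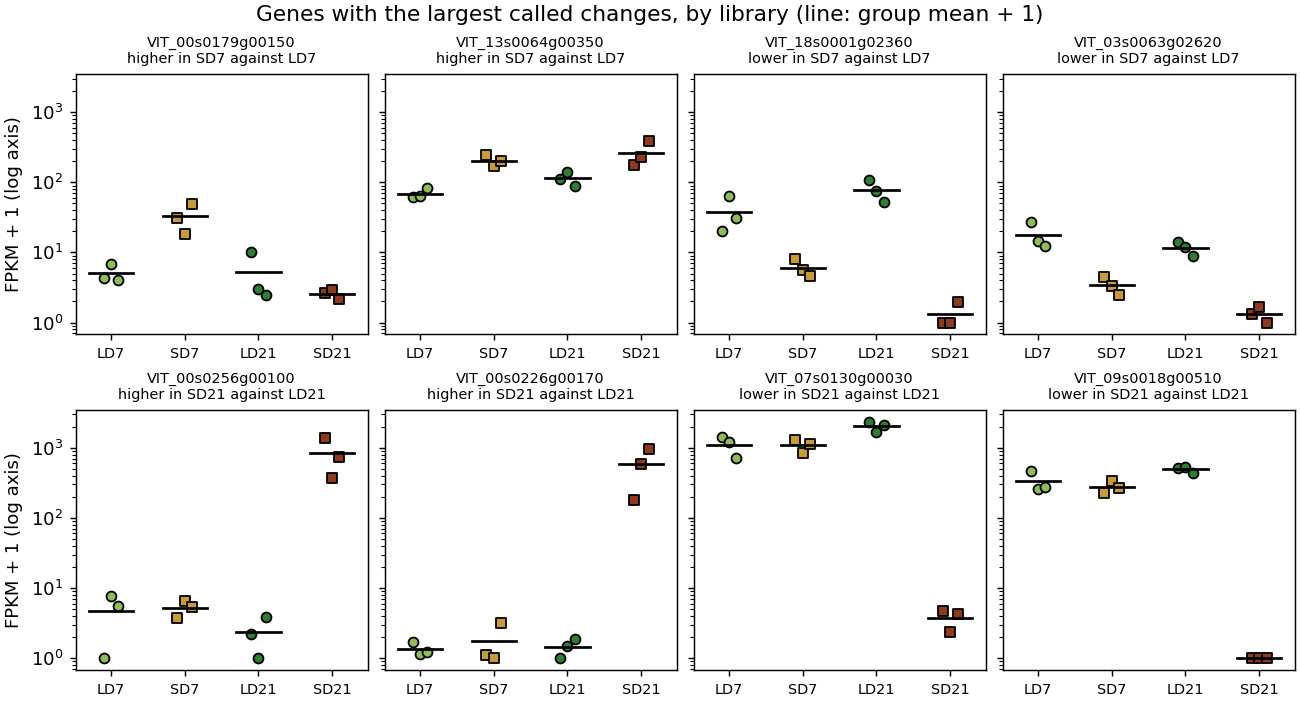
FPKM + 1 on a log axis for the named genes of the day 7 (upper row) and day 21 (lower row) photoperiod comparisons, with 1 point per library (n = 3 per group), and lines at the group mean FPKM plus 1. The SD21 points of VIT_07s0130g00030 average 2.76 FPKM against 2048 in LD21, and those of VIT_09s0018g00510 are all listed at 0.

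In all, 14921 genes were called in SD21 against LD21, 5376 higher and 9545 lower. At least 2-fold changes numbered 3092 higher and 5689 lower, at least 4-fold changes 1007 and 2016, and at least 16-fold changes 90 and 277. The libraries of SD21 and LD21 did not overlap in 69.8% of tested genes, where chance gives 10%. Genes listed at 0 in all LD21 libraries and at 5 FPKM or more in all SD21 libraries numbered 8, and the reverse held for 19. The median log2 fold change over all tested genes was -0.300. Quantile normalization moved that median to 0.012 and gave 7396 higher and 7227 lower, and median-ratio scaling, chosen after seeing the data, gave -0.056 with 7004 higher and 7686 lower. Among the 100 genes most abundant in LD7 and SD7, which this comparison does not use, 49 were higher and 39 lower in SD21. The larger side depended on the scaling, with 40 and 42 after quantile normalization and 52 and 36 after median-ratio scaling. A list ranked over all 4 groups, tried first, gave 52 and 31, but genes can enter it because they rose in SD21. Both lists were chosen after seeing the data.

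Genes that rose at least 4-fold in SD21 against LD21 lay together in 4 regions more densely than in 1000 random reorderings of the genes along the chromosomes. Windows held 10 tested genes, and the densest had a permutation p of 0.001, the smallest that 1000 reorderings can give. The densest was on chromosome 4 at 7244107 to 7498072, where 10 of 10 consecutive tested genes rose at least 4-fold and their summed FPKM went from 57.7 ± 21.1 (SD, n = 3) in LD21 to 404 ± 87.6 in SD21. On chromosome 10 at 5939778 to 6185676, 10 of 12 rose at least 4-fold, with a median log2 fold change of 3.40 and a summed 6.0 ± 1.8 FPKM in LD21 and 242 ± 93.6 in SD21. The other 2 were called lower, and all 12 together summed to 32.6 ± 1.8 and 251 ± 91.3. On chromosome 3 at 8895243 to 9130668, 7 of 10 rose at least 4-fold, from 77.1 ± 28.9 to 438 ± 121 FPKM. All 10 together summed to 117 ± 29.4 and 480 ± 127. On chromosome 9 at 22228467 to 22464239, 8 of 11 rose at least 4-fold, from 2.19 ± 1.11 to 49.4 ± 11.6 FPKM. The sum over all 11, held mostly by the remaining 3 genes, went the other way, from 3423 ± 273 to 2565 ± 403. Of all 11, however, 9 were called higher, 0 lower and 2 were not called. Among the remaining 3, only the very short locus at 22355956 to 22356055 was lower, with a log2 fold change of -0.471, and it was not called. The locus at 22249328 to 22249484 had 3.68 (not called), and that at 22418688 to 22420791 had 1.70 (called). No region passed for genes that fell at least 4-fold (permutation p = 0.053). At day 7, where genes of any fold were scanned because few were called, none passed for genes that rose (permutation p = 0.846) or fell (permutation p = 0.071). However, 1 region passed with quantile normalization and 1 with the replicate number as a block. The scan was chosen after seeing the data, and near-identical copies lying side by side can share reads, so the values of single genes in a region are uncertain.

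**Figure D3:**
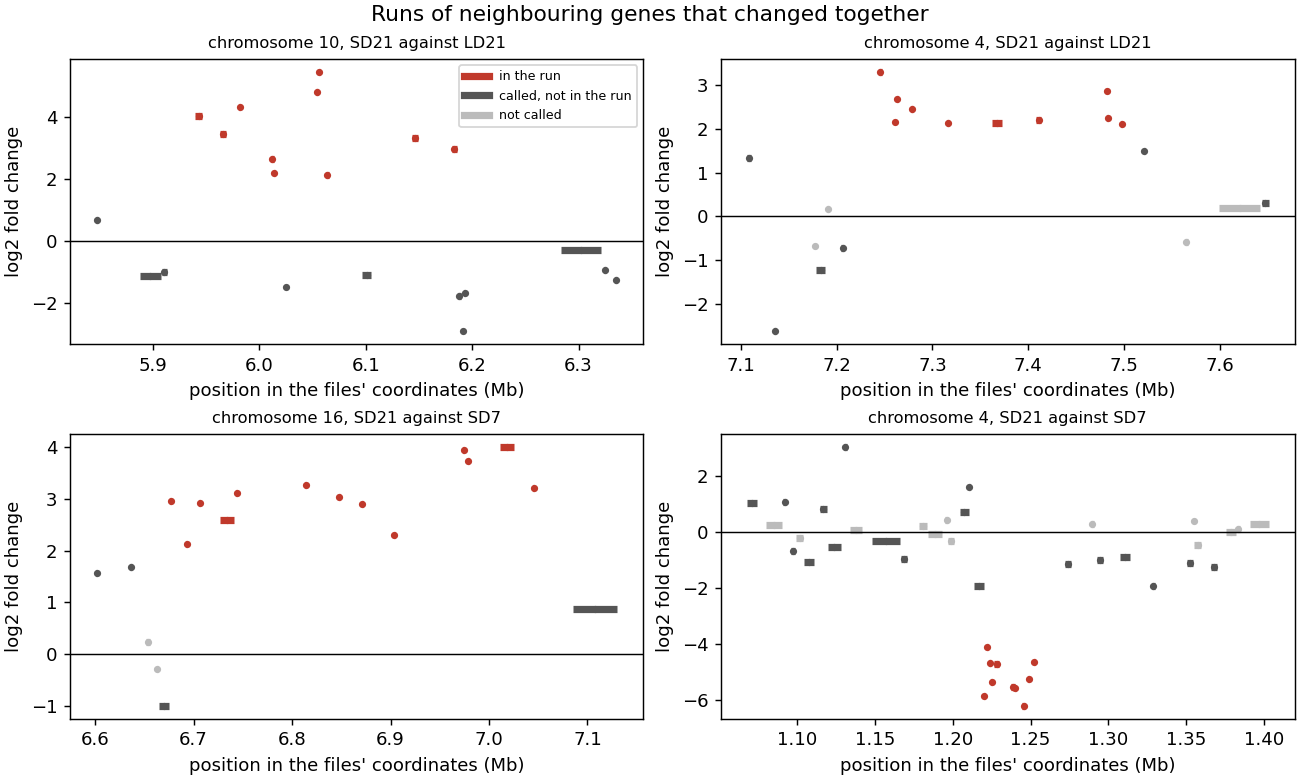
Log2 fold changes of tested genes against position in Mb around 4 regions, in SD21 against LD21 (chromosomes 10 and 4, upper row) and SD21 against SD7 (chromosomes 16 and 4, lower row). Each bar spans a locus with a dot at its middle, coloured by whether the gene is in the run, called outside it or not called, and on chromosome 4 in the upper row 10 of 10 consecutive genes rose.

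Genes higher in SD21 were unevenly spread over the 19 numbered chromosomes. They made up 29.8% of tested genes on chromosome 16 against 24.4% elsewhere (Fisher's exact test, p = 0.00053, adjusted p = 0.014 over 38 tests), 27.9% against 24.4% on chromosome 18 (p = 0.0026, adjusted p = 0.033), and 20.8% against 24.9% on chromosome 14 (p = 0.00074, adjusted p = 0.014). These tests treat genes as independent, which neighbours are not.

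Whether the photoperiod effect changed between the days was tested directly, as SD21 minus LD21 less SD7 minus LD7. The rule for named genes, applied to the difference, took the same 4 genes as in SD21 against LD21. Its limits on overlap and abundance were applied to the SD21 and LD21 libraries, so that match is partly built in. VIT_00s0226g00170 and VIT_00s0256g00100 had log2 differences of 8.21 ± 0.83 and 7.96 ± 1.09 (SE, adjusted p = 1.9e-05 and 0.00017), and their day 7 fold changes were 0.18 ± 0.59 and 0.53 ± 0.77 (adjusted p = 0.93 and 0.81). VIT_07s0130g00030, at 1109 ± 349 FPKM (SD, n = 3) in LD7 and 1089 ± 218 in SD7, had a difference of -9.14 ± 0.42 (SE, adjusted p = 7.4e-07), and VIT_09s0018g00510, at 335 ± 118 and 276 ± 58.5 FPKM at day 7, passed with an adjusted p of 1.6e-07. In all, 12045 genes were called, 4292 in the direction of a higher and 7753 of a lower effect at day 21, and 5699 and 5800 with quantile normalization or 5583 and 6017 with median-ratio scaling.

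Of the 182 genes called at day 7, 91 were called in the same direction at day 21, 43 in the opposite direction and 48 not at all. VIT_03s0063g02620 was lower at both days, with 10.7 ± 2.74 FPKM (SD, n = 3) in LD21 and 0.306, 0.692 and 0 in the SD21 libraries (log2 fold change -3.14 ± 0.32, SE, adjusted p = 5.2e-06). VIT_13s0064g00350 was higher at both, with 113 ± 25.6 and 261 ± 109 FPKM at day 21 (1.15 ± 0.27, adjusted p = 0.0027). VIT_18s0001g02360 fell further, from 77.6 ± 28.7 FPKM in LD21 to 0, 0 and 0.976 in the SD21 libraries (-5.90 ± 0.43, adjusted p = 5.1e-07), and the difference between the days was -3.38 ± 0.61 (adjusted p = 0.00078). VIT_00s0179g00150, higher at day 7, was not called at day 21 (-0.73 ± 0.50, adjusted p = 0.22), and its difference was -3.37 ± 0.71 (adjusted p = 0.0021).

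Genes higher at both days numbered 52, where independent lists would give 19.2 (Fisher's exact test, adjusted p = 8.2e-15 over 8 tests), and genes lower at both numbered 39 where 45.4 would be given (adjusted p = 0.23). Genes higher at day 7 and lower at day 21 numbered 10 where 34.1 would be given (adjusted p = 8.4e-09), and the reverse held for 33 where 25.6 would be given (adjusted p = 0.13). These comparisons share no library, but the same fit over all 12 libraries gave the spread of each gene in both. The lists are therefore not independent, and Fisher's exact test also treats genes as independent, which neighbours are not. The count of 91 was 0 without LD7 replicate 1 or LD7 replicate 2 (limma, with 2389 and 2158 genes at an unadjusted p under 0.05 in SD7 against LD7), 5 without LD7 replicate 3, 17, 3 and 30 without SD7 replicates 1, 2 and 3, 35 without LD21 replicate 2 and 51 without SD21 replicate 1. Some processing choices, given below, lowered the count of 91 as well. Across genes, which are not independent replicates, the fold changes of the days correlated with r = 0.155 (Spearman 0.21).

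Under continued LD, the shoot tips changed moderately between the days. In LD21 against LD7, 2296 genes were higher and 1667 lower, 357 and 579 of them at least 2-fold. VIT_14s0006g00600 (chromosome 14, 14611224 to 14612521) was listed at 0 in the LD7 libraries and at 57.2, 29.7 and 34.1 FPKM in the LD21 libraries (adjusted p = 0.039), and VIT_05s0062g01380, a locus of 142 bp on chromosome 5 at 20251496 to 20251637, at 0 in LD7 and at 42.9, 53.6 and 10.2 in LD21 (adjusted p = 0.019). VIT_09s0002g08510 (chromosome 9, 9571451 to 9574374) stood at 8.94, 55.9 and 81.8 FPKM in LD7 and at 0, 0 and 0.120 in LD21 (log2 fold change -5.12 ± 0.85, SE, adjusted p = 0.0054). VIT_19s0015g00990 (chromosome 19, 9076602 to 9078438) stood at 12.6, 46.6 and 29.3 in LD7 and was listed at 0 in LD21 (adjusted p = 0.035). Listed zeros also varied among libraries of 1 SD group. VIT_14s0006g00600 was at 22.0, 0 and 34.6 FPKM in SD7 and at 28.6, 0 and 0 in SD21. VIT_05s0062g01380 was at 39.6, 20.0 and 0 in SD7 and at 0 in all SD21 libraries. VIT_19s0015g00990 was at 39.3, 35.7 and 37.1 in SD7 and at 102, 0 and 9.94 in SD21.

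Of the 100 genes most abundant in SD7 and SD21, which this comparison does not use, 60 fell and 4 rose over this interval. After quantile normalization 50 fell and 6 rose, and after median-ratio scaling 61 and 1. On chromosome 7 at 9125190 to 9257623, 3 of 5 consecutive genes rose at least 4-fold, from a summed 139 ± 67.2 to 691 ± 365 FPKM, or from 145 ± 69.4 to 707 ± 371 over all 5 (SD, n = 3, permutation p = 0.001, the smallest possible). On chromosome 8 at 13066137 to 13125212, 4 of 4 fell, from 71.3 ± 62.0 to 0.921 ± 1.14 FPKM (permutation p = 0.002). Over all genes, the direction of the split depended on the scaling, with 1571 higher and 1908 lower after quantile normalization and 1217 and 2006 after median-ratio scaling. The count of 3963 was 2615, 1606 and 1358 without LD7 replicates 1, 2 and 3 and 1388 without LD21 replicate 2. VIT_14s0006g00600 and VIT_19s0015g00990 lost their calls without any 1 of the 6 libraries compared (adjusted p up to 0.109 for each), and VIT_05s0062g01380 without any but LD21 replicate 3 (up to 0.0756).

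Under SD, the change between the days was far wider, with 5113 genes higher and 8235 lower in SD21 than in SD7, 2566 and 4302 of them at least 2-fold. VIT_00s0226g00170 rose from 0.0913, 0 and 2.16 FPKM in the SD7 libraries to 579 ± 397 (SD, n = 3) in SD21 (log2 fold change 8.28 ± 0.59, SE, adjusted p = 1e-06), and VIT_11s0016g05430 (chromosome 11, 4812623 to 4814041) from 2.66 ± 0.56 to 745 ± 259 FPKM (7.63 ± 0.27, adjusted p = 5.8e-08). VIT_07s0130g00030 fell from 1089 ± 218 to 2.76 ± 1.22 FPKM (-8.22 ± 0.30, adjusted p = 5.8e-08), and VIT_09s0018g00510 went from 276 ± 58.5 FPKM to the listed 0 (adjusted p = 7.5e-09). With quantile normalization 6773 genes were higher and 6560 lower, and with median-ratio scaling 6316 and 7049. Of the 100 genes most abundant in LD7 and LD21, which this comparison does not use, 52 fell and 18 rose. After quantile normalization 56 fell and 12 rose, and after median-ratio scaling 49 and 25. The test of whether the time change differs between photoperiods is the same contrast as the difference of the photoperiod effects, with its 12045 genes.

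Regions of neighbouring genes that changed at least 4-fold in SD21 against SD7 numbered 6 higher and 2 lower. The permutation p was 0.001 for the densest window of each direction, the smallest possible, and does not hold for each region. For rises, random reorderings reached up to 6 such genes in a window, as many as the chromosome 5 region at 1232006 to 1264645 held. On chromosome 16 at 6676141 to 7045848, 13 of 13 genes rose at least 4-fold, from a summed 192 ± 139 FPKM (SD, n = 3) in SD7 to 1477 ± 119 in SD21. The same genes summed to 595 ± 62.9 in LD7 and 1031 ± 359 in LD21. On chromosome 5 at 1232006 to 1264645, 6 of 6 rose at least 4-fold, from 200 ± 91.3 to 3011 ± 979 FPKM. At 7708032 to 7952979, 9 of 16 rose at least 4-fold. The regions on chromosomes 4, 9 and 10 described for day 21 appeared again, from comparisons that share the SD21 libraries. On chromosome 4 at 1219941 to 1252699, 10 of 10 genes fell at least 4-fold with a median log2 fold change of -5.30, from a summed 1415 ± 1032 to 18.6 ± 9.92 FPKM. On chromosome 3 at 736434 to 927965, 21 of 25 fell at least 4-fold, from 611 ± 141 to 92.3 ± 34.5 FPKM. Of all 25 genes, which summed to 694 ± 162 and 139 ± 43.8, 24 were called lower and 1 higher.

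**Figure D4:**
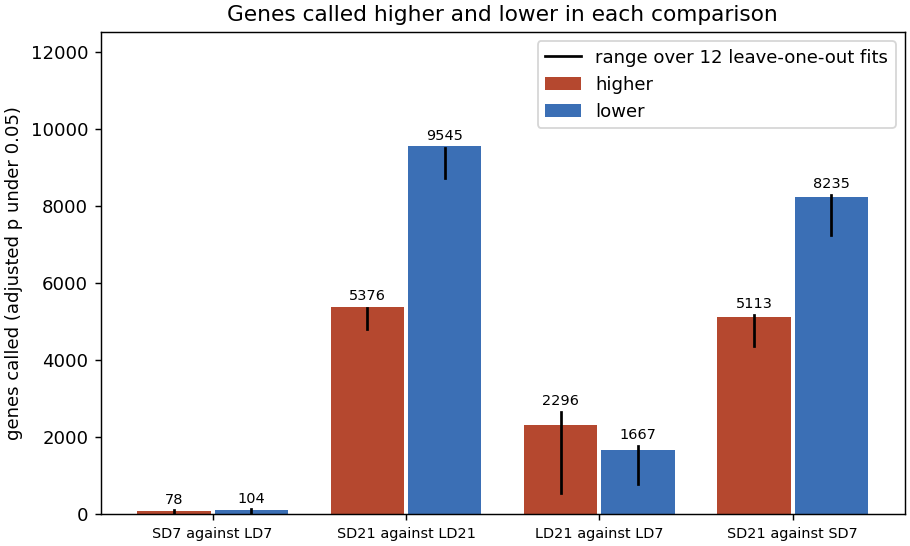
Number of genes called at an adjusted p under 0.05, on an axis from 0, as bars for genes higher and lower in each comparison, with black lines for the range over the 12 fits that each leave out 1 library. SD21 against LD21 has 5376 higher and 9545 lower genes, and SD7 against LD7 has 78 and 104.

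Over all 21848 tested genes, the time changes under LD and SD correlated weakly and negatively, with r = -0.128 (Spearman -0.177) across genes, which are not independent replicates. These comparisons share no library. Among the genes called over time in both photoperiods, opposite directions were more common. Of 2656 such genes, 1860 (70.0%) differed in direction, 1202 higher with time under LD and lower under SD where independent lists would give 865, and 658 the reverse where 390 would be given (Fisher's exact test, adjusted p = 8.4e-51 and 1.1e-51). Genes higher in both numbered 370 against 537, and genes lower in both 426 against 628 (adjusted p = 3.8e-19 and 3.5e-27). Here too both lists took the spread of each gene from the same fit, and the tests treat genes as independent. With quantile normalization the opposite classes held 741 and 829 genes, where 471 and 590 would be given, so which of them was larger depended on the scaling. The region on chromosome 7 at 9125190 to 9257623, picked for its rise in LD21 against LD7, was of the first kind. With time, 4 of its 5 tested genes were higher under LD and 5 of 5 lower under SD. Only the fall under SD comes from libraries that the choice did not use. The count of 1860 was 748 without LD7 replicate 2, 574 without LD7 replicate 3, 1108 without LD21 replicate 1 and 628 without LD21 replicate 2. The labels give no harvest or sequencing batch, so in these time comparisons day and any batch of that day cannot be told apart.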

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

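The tests of composition, of scaling, of distance between neighbours and of depth were chosen after the results were seen, and those of run genes' deviations, of single libraries and of other splits before. The photoperiod effect differed between day 7 and day 21 by the test of the difference itself, with 12045 genes called. Among the named genes, the log2 difference (day 21 minus day 7) was -3.37 for VIT_00s0179g00150, -3.38 for VIT_18s0001g02360, 7.96 for VIT_00s0256g00100, 8.21 for VIT_00s0226g00170 and -9.14 for VIT_07s0130g00030. VIT_09s0018g00510, listed at 0 in SD21, has no fold and passed with an adjusted p of 1.6e-07.

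Many more genes were called at day 21 (14921) than at day 7 (182). A depth difference between SD21 and LD21 is argued against by a ratio of mean relative depths of 1.12, and a single library apart from its group by a lowest count of 13797 with each of the 6 libraries left out in turn. Longer exposure to the short photoperiod, which the design names, was not tested and is left as a hypothesis. No samples separate days of exposure from the sampling day.

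More genes were lower than higher in SD21 against LD21. A single dominant locus may add to this, but with the most abundant SD21 gene removed and totals set equal the median log2 fold change was still -0.305, against -0.415 with it, and without the 100 most abundant genes it was -0.14. Scaling of FPKM to totals cannot be told apart from a wide fall, because median-ratio scaling, which gave 52.3% lower calls, centres the fold changes by construction. Whether the amount of many transcripts fell was not tested, since FPKM hold no absolute amounts.

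Neighbouring genes changed together in SD21 against LD21, where fold changes of all adjacent genes correlated with r = 0.139, and to a like degree in SD7 against LD7 (0.136) and LD21 against LD7 (0.13). For overlapping or touching genes r was 0.598, 0.36 and 0.32 in that order, and for those over 20 kb apart 0.143, 0.107 and 0.105. Reads shared between overlapping or touching loci are argued against as the whole cause, since in SD21 against LD21 the 95% interval for genes over 20 kb apart was 0.112 to 0.174, against an r of 0.007 for genes 10 apart. Reads shared between near-identical copies cannot be told apart from shared regulation, as both would raise the correlation of deviations from the group means, whose median was 0.758 over 24 adjacent pairs within the runs and 0.088 over all 19627 pairs.

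In each pairwise comparison the 10 splits of 6 libraries are too few for a share under 0.05. The real split was the 1 of 10 that called as many genes in all 4, with 182 in SD7 against LD7 (highest other 2), 14921 in SD21 against LD21 (highest other 2), 3963 in LD21 against LD7 (highest other 1) and 13348 in SD21 against SD7 (highest other 2). For the difference of the effects, 6 of 100 splits of the photoperiod labels within each day, the real one included, called at least 12045 genes (highest other 12730). All 14 of the 99 other splits with at least 0.5 of the real count kept the SD21 and LD21 libraries apart and regrouped those of day 7, so the count of splits follows the day 21 structure of the samples. Chance in the grouping of the day 7 libraries is therefore not excluded, and for that of the day 21 libraries no drawn split that mixed SD21 with LD21 reached 0.5 of the real count.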

How the results depend on the processing

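The named genes of SD21 against LD21, of SD21 against SD7 and of the difference kept their calls and directions in every alternative, and over all named genes 319 of 376 alternative values kept the call, 57 lost it and 0 reversed, the losses being in SD7 against LD7 and LD21 against LD7. The 2-fold limit and the adjusted p of 0.01 are not among the 376. At 0.01, no named gene of SD7 against LD7 passed (lowest limma adjusted p = 0.017). In LD21 against LD7 only VIT_09s0002g08510 did (0.0054). SD7 against LD7, with 182 genes, had 108 without the trend, 83 without the filter, 82 with only the groups compared, 117 with median-ratio scaling, 80 at 2-fold and 1 at an adjusted p of 0.01. For genes called at both days in 1 direction, 91 became 52, 41, 34, 57, 24 and 0 in that order (limma, with 3258 genes at an unadjusted p under 0.05 at day 7). The 2-fold limit gave 8781 genes in SD21 against LD21, 936 in LD21 against LD7, 6868 in SD21 against SD7 and 285 opposite over time, and an adjusted p of 0.01 gave 921 in LD21 against LD7 and 362 opposite over time. The stricter thresholds lower counts by construction, and the cause of the other changes was not tested. With each library left out, counts ran from 0 to 208 in SD7 against LD7, 13797 to 14856 in SD21 against LD21, 10847 to 11833 in the difference, 1358 to 4408 in LD21 against LD7, 11875 to 13444 in SD21 against SD7, 0 to 95 for both days and 574 to 2023 for opposite over time, and the first component from 60.1% to 69.4% (lowest without SD21 replicate 3). The lowest counts came without LD7 replicate 2 for day 7 (0, with 2158 genes at an unadjusted p under 0.05), LD7 replicate 1 or 2 for both days (0) and LD7 replicate 3 for LD21 against LD7 (1358) and opposite over time (574), and the report names the others that moved a count over 1.5 times.

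With the replicate number as a block, SD7 against LD7 had 74 genes and both days 39. The block ended the calls of VIT_00s0179g00150, VIT_13s0064g00350 and VIT_18s0001g02360 in SD7 against LD7 (limma adjusted p = 0.0731, 0.0596 and 0.0647) and of VIT_19s0015g00990 in LD21 against LD7 (0.0548). No clear pairing by replicate number was seen, though a weak one is not excluded. Of 18 same-number pairs, 2 correlated above 0.1 in their deviations (highest 0.203), and 11 of 36 best matches were to the same number. The 4 regions of SD21 against LD21 were found again in 4 with quantile normalization, median-ratio scaling and the block and in 3 with windows of 20 genes, and the 8 of SD21 against SD7 in 8, 8, 8 and 7. SD7 against LD7 had 0 regions, and 1 with quantile normalization or with the block. Median-ratio scaling, composition and the region alternatives were chosen after seeing the data. The gene list tests and their alternatives (estimated correlation, fry, block) were not run for want of gene names, and the fit of only the groups compared gives no value for the difference. Unknown absolute depth limits statements on genes listed at 0 and near 0.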

Other observations

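Outside the comparisons above, the regions found in 1 comparison were followed through the others. The 13 tested genes on chromosome 16 at 6676141 to 7045848 were picked because they rose in SD21 against SD7. In LD21 against LD7, which shares no library with that choice, 13 of 13 were not called, with a median log2 fold change of 0.66. In SD7 against LD7, 2 were lower and 11 not called, and in SD21 against LD21, 4 were higher and 9 not called, but each of these uses libraries the choice was made on. The region on chromosome 4 at 1219941 to 1252699, picked for its fall in SD21 against SD7, had a median log2 fold change of -1.12 in LD21 against LD7 with 10 of 10 genes not called. Its summed FPKM was 338 ± 91.4 in LD7 and 287 ± 445 in LD21 (SD, n = 3). The region on chromosome 2 at 3722110 to 3822797 was found only in the difference, which uses all 4 groups. There, the difference of the effects was at least 4-fold, toward a higher effect at day 21, for 9 of 14 genes. These 9 summed to 222 ± 39.8 FPKM in SD7 and 530 ± 161 in SD21. In LD7 they summed to 381 ± 86.4 and in LD21 to 156 ± 37.5. Of all 14, SD21 against SD7 called 5 higher and 2 lower, with 7 not called.

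Fold changes went weakly with the sequence a locus spans, most in LD21 against LD7 (Spearman 0.106 across genes, which are not independent replicates). It was -0.057 in SD21 against LD21, -0.013 in SD21 against SD7 and 0.007 in SD7 against LD7. Median log2 fold changes of loci of 8205 bp or more were 0.172 in LD21 against LD7 and -0.365 in SD21 against LD21. For loci of up to 1215 bp they were 0.007 and -0.199.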
